A study of Canis lupus familiaris with 6 samples.

How the data were processed

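RNA was measured by high-throughput sequencing in dog tissue that the labels give as uterus. The extraction protocol in the labels names the uterus but also asks for secretions of the prostate, a male gland, to be removed, and this conflict was not resolved. Pyometra is a suppurative bacterial infection of the uterus of the bitch, and the labels give 3 samples from normal uterus and 3 from uterus with pyometra. Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with an Illumina TruSeq RNA kit, and an Illumina HiSeq instrument was used for sequencing. Nothing in the labels says whether the 3 samples of a group came from separate animals, so p-values measure the spread between these samples. The stage of the oestrous cycle and the cause of the pyometra are not given in the sources used here, so a difference between the groups cannot be assigned to the disease apart from the cycle stage.

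Each sample came with 1 table of 121359 features with 2 measured columns. Per the file headers, the first is a read count per feature. From the values, the authors deposited estimated counts (expected counts per cluster), not scaled for depth or length, and the tool that estimated them is not given in the sources used here. They were taken as estimates because 5.57% to 6.05% of the features with a count in a library had a count that was not whole (differing from the nearest whole number by more than 1e-09). Per the file headers, the second column is FPKM, the count divided by the length of the feature and the depth of the library. The count, the FPKM and the column total together give the effective length that the authors divided by. For the 10172 features with more than 100 counts in every library this length differed from the median of the 6 libraries by less than 0.569% in 99% of the values, so the FPKM values were scaled to the column totals. The submitters' processing notes name CASAVA, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3, without giving their roles. HISAT2, StringTie and featureCounts commonly align reads to a genome, assemble transcripts from them and count them in genes, whereas the cluster identifiers and the counts that are not whole are of a kind that de novo assembly with estimated counts gives. The genome build and the step that made the features are not given in the sources used here, so what a cluster and its count stand for was not settled.

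The features are named as numbered clusters, and the files do not pair them with gene names, sequences or positions. None of the identifiers matched the 43286 genes of the reference table used here, which is for the assembly UU_Cfam_GSD_1.0. Gene names are therefore not reported, a cluster is not assumed to be 1 gene, and no coordinates are given. The gene lists and the protein-coding subset that had been fixed before the data were examined could not be applied. The rule for the items to name had been to take the genes with the largest changes among those with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the 3 values of one group and the 3 of the other. It was applied to clusters without its condition of a gene symbol, and shortened to 2 clusters per direction, after the identifiers had been seen. Its part on the 3 most abundant genes of each group was applied without printing identifiers. Its other parts, a panel of named genes and the members of the lists, could not be applied.

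Counts were rounded to whole numbers. Clusters were kept with edgeR's filterByExpr at its defaults (10 counts at the median library size in at least 3 libraries and 15 in all). Library sizes were the column totals, scaled with TMM factors. Pyometra was compared with normal in all 6 libraries with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust estimation, no covariates). P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested clusters, and a cluster was called at an adjusted p under 0.05. A standard error of a log2 fold change is the estimate divided by the square root of its F statistic. CPM values are TMM-normalised, whereas shares of counts are of the column totals. Single values per library were compared with exact two-sided permutation tests (scipy 1.17.1), for which 3 against 3 libraries cannot give a p under 0.1. A count of 0 in a library allows up to 3 counts, and this floor, like the 95% exact (Clopper-Pearson) intervals, covers counting error only, since PCR copies were not removed by molecular identifiers as far as the sources say.

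The fit was tested on 10 simulated data sets of this comparison, each with negative binomial counts for between 28701 and 28881 tested clusters and 200 changed clusters before filtering. Of the changed clusters that were tested, 47.7% of those with a 4-fold change and 6.41% of those with a 2-fold change were called, with no call in the wrong direction. Of the unchanged clusters, 4.48% had an unadjusted p under 0.05, and 11.8% of all calls were false, more than the nominal 5%. The real comparison called 14139 clusters, far more than the 200 changed in a simulation. The shares recovered and the share of false calls depend on how many clusters change. They therefore do not give the power or the false share of the real calls. Libraries were also compared in pairs for duplicates. Over clusters with at least 20 counts in a pair, chi-square divided by its degrees of freedom was 7.76 for normal 1 and normal 3, the closest pair, and up to 76.4 within groups, so no 2 libraries agreed within sampling noise.

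The alternatives were RLE, upper-quartile and no composition factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter (at least 1 count) and a stricter filter (1 CPM in 3 libraries), an adjusted p under 0.01, a minimum absolute log2 fold change of 1, the number in the title as a block, each library left out, and limma-trend on log2(FPKM + 1). Chosen after seeing the data were whole counts alone, an effective length of at least 500 bases, a lowess correction for length, and limma-trend on log2(TPM + 1) with the FPKM rescaled to a sum of 1000000 per library. The minimum of 10 counts for clusters found in 1 group alone was chosen after values at a minimum of 100 had been seen, and counts at both are given.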

Results

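The transcriptomes of normal uterus (n = 3) and of uterus with pyometra (n = 3) were compared to find which transcripts differ in level in the infected organ. The stage of the oestrous cycle is not given for either group, so it is not separated from the disease in any comparison. The libraries held between 15400360 and 17157278 counts. The mean was 16209920 ± 706715 counts in the normal group and 16365083 ± 702610 counts in the pyometra group (SD, n = 3). Counts were given for 121359 clusters of transcript sequences, which the files do not pair with gene names. In each library, 97.2% to 98.1% of the counts fell on 39003 clusters whose identifiers share 1 prefix, with a median effective length of 874 bases. The other 82356 clusters had a median of 214 bases and made up the rest, under 74979 prefixes in all. Between 76193 and 94878 clusters had a count in a library, and between 28432 and 34567 had at least 10.

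The libraries of the 2 groups stood far apart. The first principal component of log2 CPM held 78.8% of the variance and parted the 3 normal libraries from the 3 pyometra libraries. Across clusters, the Pearson correlation of log2 CPM was 0.951 to 0.978 between normal libraries, 0.938 to 0.962 between pyometra libraries and 0.720 to 0.770 between a normal and a pyometra library. Clusters are not independent replicates, so these values describe the libraries. The biological coefficient of variation was 0.279 within the normal group and 0.365 within the pyometra group. Of 3 libraries some pair is always the closest, so the library outside that pair is named here as description only. Pyometra 2 had a correlation of 0.944 and 0.938 to pyometra 1 and pyometra 3, which correlated at 0.962 with each other. Normal 2 had a correlation of 0.951 and 0.960 to normal 1 and normal 3, which correlated at 0.978. The biological coefficient of variation was 0.277 without pyometra 2, against 0.410 without pyometra 1 and 0.381 without pyometra 3. It was 0.153 without normal 2, against 0.299 without normal 1 and 0.362 without normal 3. Normal 2 had 76193 clusters with a count, against 94878 in normal 1 and 92762 in normal 3.

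**Figure D1:**
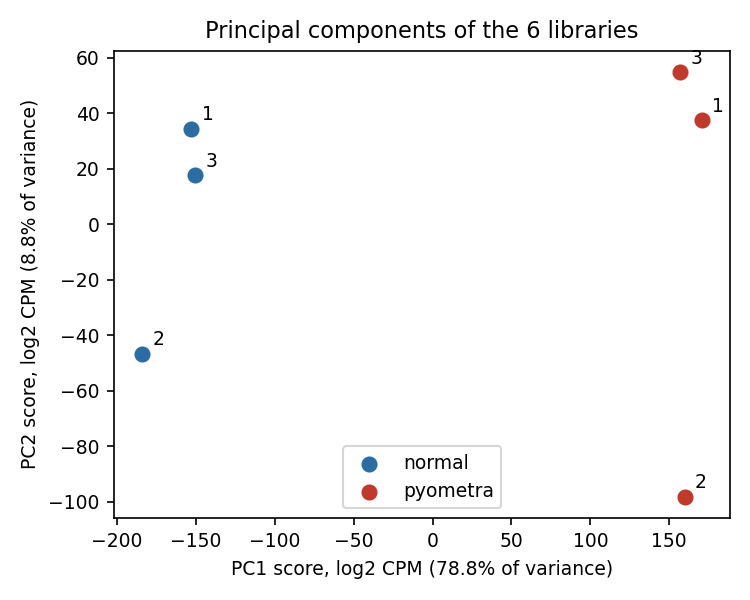
Scores of the 6 libraries (points, numbered by replicate) on the first 2 principal components of log2 CPM over the tested clusters, with normal in blue and pyometra in red. The horizontal axis holds 78.8% of the variance and parts the groups; the vertical axis holds 8.78% and parts libraries within both groups.

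A large part of the measured transcriptome differed in level between normal uterus and uterus with pyometra. Of 31088 clusters tested, 14139 (45.5%) were called, of which 7439 rose and 6700 fell in pyometra. Rises were larger than falls. The median called rise was 4.05-fold and the median called fall 3.01-fold, and 2262 clusters rose by more than 8-fold against 944 that fell by as much. Above 32-fold there were 903 rises and 116 falls. These fold classes set the 415 risen clusters without a count in any normal library, and the 72 fallen ones without a count in any pyometra library, at the floor of 3 counts per library. In 14039 of the 14139 called clusters all 3 values of one group lay above all 3 of the other. This held for 59.6% of all tested clusters, where chance gives 10% for 3 against 3 libraries. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Upper-quartile factors turned the balance to 6431 rises and 8269 falls and library size alone to 5361 and 10639, with the median log2 fold change of all tested clusters moved from 0.00 to -0.18 and -0.42, so the split between rises and falls, and the sizes of both, are relative to the TMM scaling.

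**Figure D2:**
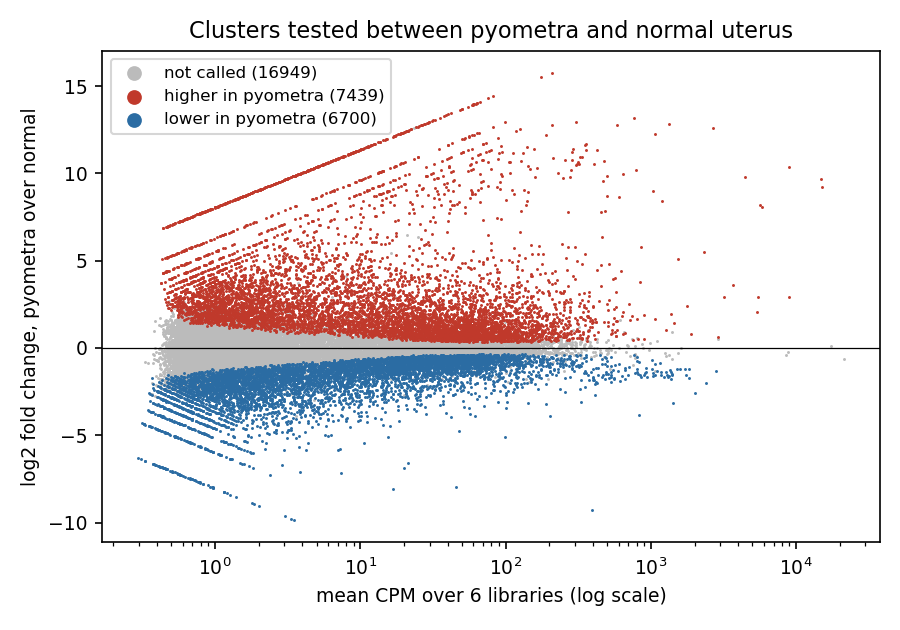
Log2 fold change of pyometra over normal (vertical axis) against the mean CPM over the 6 libraries (horizontal axis, log scale) for the 31088 tested clusters. Red points are the 7439 clusters called higher and blue points the 6700 called lower in pyometra; the upper straight line of red points is made of clusters without a count in the normal libraries, whose fitted fold change depends on a prior count.

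Risen clusters made up most of the RNA counted in the infected uterus. The 7439 risen clusters held 17.8% ± 1.32 of the counts in normal and 54.7% ± 0.755 in pyometra libraries (SD, n = 3). The 6700 fallen clusters went from 36.8% ± 1.75 to 12.2% ± 0.308. The clusters that were not called went from 43.7% ± 0.325 to 31.6% ± 0.739 of the counts. Clusters too low to be tested held 1.78% ± 0.136 and 1.56% ± 0.171. The classes were formed from these same libraries, so the shares describe the calls and are no independent test of them. The gain was concentrated. Of the 36.9 percentage points gained by risen clusters, 10 clusters held 33.3% and 100 clusters held 54.3%. Among the fallen clusters the loss was more spread out, and the 10 of them with the largest loss held 10.3% of it. This leaves out the share lost by clusters that were not called.

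**Figure D3:**
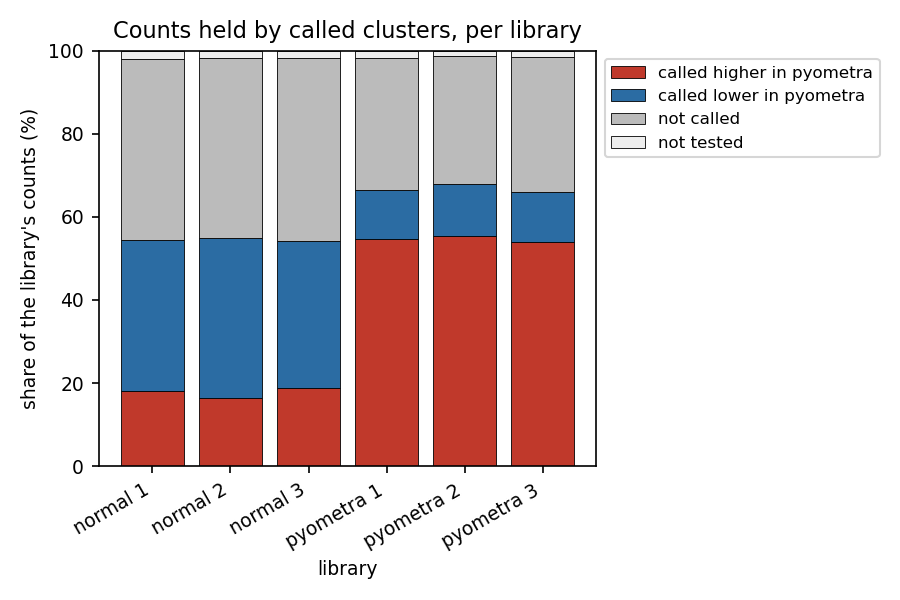
Share of each library's counts (vertical axis, percent) held by clusters called higher in pyometra (red), called lower (blue), not called (grey) and not tested (light grey), for the 6 libraries. Risen clusters hold 16.3% to 18.9% in the normal libraries and 53.9% to 55.4% in the pyometra libraries.

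Most of the 10 most abundant clusters in pyometra were much less abundant in normal uterus. Of the 10 most abundant clusters in the pyometra group, 8 rose, 6 of them by more than 8 on the log2 scale, and 2 were not called. These 10 were picked by their level in pyometra, which favours rises, so the balance is description only. The most abundant one took 0.00569% ± 0.00168 of the counts in normal and 2.60% ± 0.877 in pyometra libraries (SD, n = 3), a log2 fold change of 9.24 ± 0.49 (SE; edgeR adjusted p = 1.35e-05). The next took 0.00424% ± 0.00191 and 2.58% ± 0.585 (log2 fold change 9.66 ± 0.52, SE; edgeR adjusted p = 1.55e-05). In the normal libraries these clusters ranked 3883 and 5266 by abundance. The third most abundant cluster in pyometra was the second in normal. It took 1.93% ± 0.0115 of the counts in normal and 1.55% ± 0.0407 in pyometra libraries (SD, n = 3), with a log2 fold change of 0.10 ± 0.20 on the TMM scale (SE; edgeR adjusted p = 0.724), and was not called. Its sign followed the scaling, with a log2 fold change of -0.32 with library size alone, and it was called lower on the log2(TPM + 1) scale alone (limma adjusted p = 0.00558, against 0.101 to 0.892 under the other alternatives).

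Of the 10 most abundant clusters in the normal group, 6 fell, 4 were not called and none rose (edgeR). These 10 were picked by their level in normal, which likewise favours falls. The first took 3.01% ± 0.453 of the counts in normal and 1.46% ± 0.125 in pyometra libraries, with a log2 fold change of -0.64 ± 0.24 (SE) that missed the threshold (edgeR adjusted p = 0.0585). The third, with 1.12% ± 0.113 and 0.624% ± 0.0714 of the counts, was not called either (edgeR adjusted p = 0.132). Whether they were called depended on the setting: with library size alone both were called lower (edgeR adjusted p = 0.00315 and 0.00525), and without pyometra 2 the third was called lower (edgeR adjusted p = 0.0352). Both were also called lower with upper-quartile factors (edgeR adjusted p = 0.0187 and 0.0413) and with limma-voom (limma adjusted p = 0.00775 and 0.0247). DESeq2 called the first lower but not the third (DESeq2 adjusted p = 0.0301 and 0.160). With RLE factors neither was called (edgeR adjusted p = 0.0799 and 0.179). Over all alternatives run with edgeR, DESeq2 or limma, the adjusted p ranged from 5e-22 to 0.102 for the first and from 1.12e-08 to 0.283 for the third, with both lowest when low counts were not filtered. These lowest values stood far below the rest. Under the other settings the lowest was 0.00075 for the first and 0.00241 for the third (limma adjusted p on log2(TPM + 1)). The 6 that fell had log2 fold changes between -1.34 and -3.15. As a whole, the 10 most abundant clusters of each library took 9.53% ± 0.916 of the counts in normal and 14.98% ± 0.568 in pyometra (SD, n = 3). The exact permutation p of this difference was 0.1, the smallest that 3 against 3 libraries can give.

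The 2 clusters with the largest rises under the rule for named clusters were not detected in normal uterus. Cluster-66734.6288, with an effective length of 7413 bases, had no count in any normal library and 416 ± 141 CPM in pyometra (SD, n = 3). It was at least 2597-fold higher, taking 3 counts per library as the floor (edgeR adjusted p = 2.61e-05). Cluster-66734.34296, of 4696 bases, likewise had no count in normal libraries and 350.0 ± 135 CPM in pyometra, at least 2183-fold higher (edgeR adjusted p = 5.11e-05). Both belong to the clusters counted in pyometra alone, which are unevenly numbered: 88 of these are numbered 6000 to 6999 and 100 are numbered 34000 to 34999. The counts of the first were not whole, so its fold rests on estimated counts. The 2 clusters with the largest falls under the same rule had few counts in pyometra. Cluster-66734.19059, of 2124 bases, fell from 33.5 ± 14.1 CPM to 0.117 ± 0.203 CPM, a log2 fold change of -8.06 ± 0.78 (SE; edgeR adjusted p = 0.000249). Its 5 counts in pyometra, all in 1 library, against 1872 in normal put the fold between 121 and 873 (95% exact interval, counting error only). Without pyometra 1, which held these counts, it was at least 158-fold lower, and without pyometra 3 the log2 fold change was -7.45. Cluster-66734.24529, of 9259 bases, fell from 90.7 ± 36.7 CPM to 0.365 ± 0.394 CPM, a log2 fold change of -7.97 ± 0.61 (SE; edgeR adjusted p = 0.00012). Without pyometra 2, which held 11 of its 15 pyometra counts, the log2 fold change was -9.28. The calls and directions of all 4 held in each of the 73 values that the alternatives gave. All 4 were picked for large changes in these same libraries, so this is no independent support for them. The refit on whole counts alone gave a value for Cluster-66734.34296 only, since the other 3 had counts that were not whole.

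**Figure D4:**
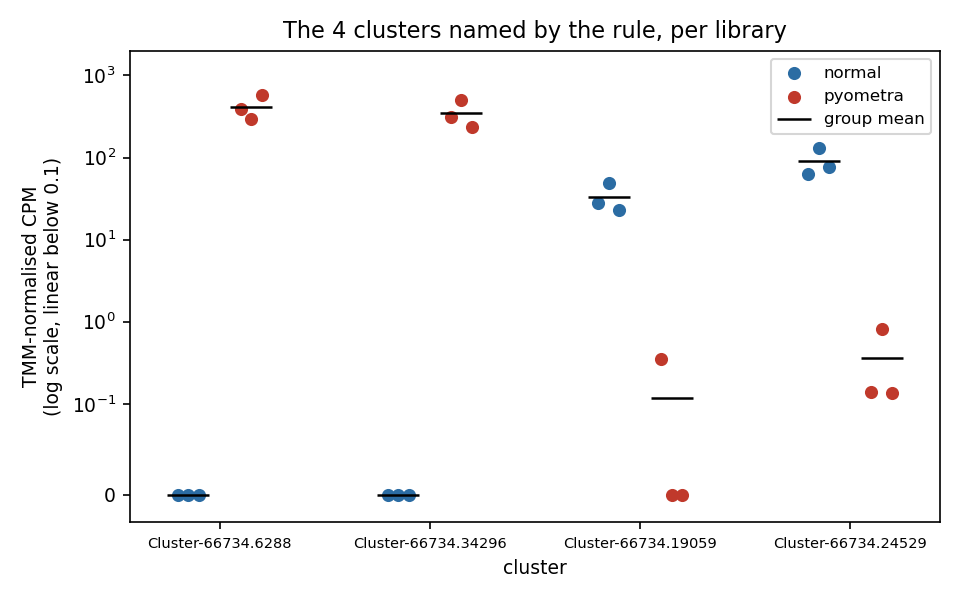
TMM-normalised CPM (vertical axis, log scale, linear below 0.1) of the 4 named clusters in the normal (blue) and pyometra (red) libraries, with a bar at each group mean. The 2 risen clusters lie at 0 in all normal libraries and at 238 to 570.4 CPM in pyometra; the 2 fallen clusters lie at 23.2 CPM or more in normal and under 1 CPM in pyometra.

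Calls were more frequent among abundant clusters, and rises outnumbered falls between 10 and 1000 CPM. Of the 6940 clusters with a mean under 1 CPM, 840 rose and 1075 fell. Between 1 and 10 CPM, 2735 of 12486 rose and 2744 fell. Between 10 and 100 CPM, 3102 of 9884 rose and 2494 fell. Between 100 and 1000 CPM, 737 of 1709 rose and 357 fell. Of the 69 clusters above 1000 CPM, 25 rose and 30 fell. By length, the clusters under 500 bases had the highest share of rises among calls, with 827 rises and 488 falls among 2981 tested. Of 6246 clusters between 500 and 1000 bases, 936 rose and 1285 fell, and of 5691 clusters of 4000 bases or more, 1833 rose and 1359 fell. The balance in each class is relative to the TMM scaling, as above, and differences between the classes were not tested. The test can call smaller changes where counts are high, so more calls among abundant clusters need not mean that they change more often.

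Some clusters were counted in 1 group alone, and more often in pyometra. With at least 10 counts in every library of one group and none in the other, 437 clusters were found only in pyometra and 84 only in normal. With at least 100 counts, 93 were found only in pyometra and none in normal. The 437 held 0.653% ± 0.150 of the pyometra counts and the 84 held 0.0143% ± 0.00248 of the normal counts (SD, n = 3). The pyometra-only clusters were short, with a median effective length of 210.1 bases, but 84 of them exceeded 1000 bases. In 262 of the 437, and in 2 of the 84, a count in the group's own libraries was not whole. The sets also differed in make-up, so this contrast is not separated from it. Under the main prefix were 347 of the 437 and 25 of the 84, and the 84 had a median effective length of 713 bases. These clusters were not detected in the other group at this depth. A count of 0 allows up to 3 counts in each library, so this does not show that they were absent. Leaving out 1 library gave 510 to 611 pyometra-only and 156 to 215 normal-only clusters, the latter at least 1.5 times the number with all libraries for each library left out. Removing a library relaxes the definition, so both numbers could only rise or stay, and the rise itself says nothing about a single library.

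The FPKM values had a higher sum in pyometra. They summed to 481853 ± 21623 in normal and 734075 ± 82573 in pyometra libraries (SD, n = 3), 1.52 times as much (exact permutation p = 0.1, the smallest possible here). Most of the difference lay in clusters under 500 bases, with 138138 ± 12545 in normal and 377972 ± 81261 in pyometra (exact permutation p = 0.1). Those of 500 bases or more summed to 343715 ± 9093 and 356103 ± 5376 (exact permutation p = 0.2). The effective length averaged over counts was 4407 ± 106 bases in normal and 4115 ± 22.6 bases in pyometra libraries (exact permutation p = 0.1).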

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

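The fixed alternatives were chosen before the data were examined; whole counts alone, a minimum length, the length correction and log2(TPM + 1) were added after seeing the data. With each library left out in turn, between 11538 and 14840 clusters were called, 75.3% to 88.2% of the 14139 calls were kept in the same direction per fit, 9191 were kept in all 6 fits, and none reversed. The count of calls stayed within 1.5 times under RLE and upper-quartile factors, no composition factors, DESeq2, limma-voom, no filter, the stricter filter, a minimum log2 fold change of 1, log2(FPKM + 1), a minimum length of 500 bases and the length correction. At an adjusted p under 0.01, 8727 clusters were called and 3628 fell. Scaling by library size alone gave 10639 falls, with 33.5% of calls higher against 52.6% with TMM. Limma-trend on log2(FPKM + 1) gave 11534 falls and 32.3% higher, with a median log2 fold change of -0.31 over the clusters it tested. Upper-quartile factors gave 6431 rises and 8269 falls (43.7% higher), with a median of -0.18. Limma-trend on log2(TPM + 1) gave 25605 calls, 4251 higher and 21354 lower, with 140 calls reversed, a median log2 fold change of -0.64 and 68489 clusters tested. Rescaling divides the pyometra libraries by their larger FPKM sum, so changes on the TPM scale are relative to this median. FPKM is scaled to the column totals with no composition factor, like library size alone, which gave a median of -0.42 against -0.35 for FPKM over the clusters tested with TMM. Clusters with whole counts alone gave 9069 calls, 4807 higher and 4262 lower, among fewer clusters tested (21487). The numbers in the titles were not taken to pair the samples: same-numbered normal and pyometra libraries had correlations of 0.08, 0.15 and 0.01 in their deviations from the group means, not all over 0.1, and normal 1 correlated best with pyometra 3. With the number as a replicate block, 13801 clusters were called, 7355 higher and 6446 lower. The fixed gene lists, the protein-coding subset and the alternatives for files without counts were not run, since the clusters carry no gene names or biotypes and counts were given. Depth limits the clusters with few counts: 90271 of the 121359 clusters were too low to test.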

Other observations

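Of the tests below, those on clusters found in pyometra alone and on the trend with length were chosen after the result was seen, and the others before. The biological coefficient of variation was 0.365 in pyometra and 0.279 in normal, and in both groups it was lower without 1 library, 0.277 without pyometra 2 and 0.153 without normal 2. Some pair of 3 libraries has to give the lowest value, so this describes the libraries and is no test. For the 437 clusters found in pyometra alone the log2 ratio of the counts in pyometra 1 and pyometra 2 had an SD of 1.70 across clusters. The SD was 0.83 across the 7008 risen clusters with at least 10 counts in each pyometra library that were also seen in normal. These were not matched to the 437 for abundance or length, with a median effective length of 2273 bases against 210.1 for the 437. The clusters found in pyometra alone were also unevenly numbered. Of the 437, 100 had numbers from 34000 to 34999 and 88 had numbers from 6000 to 6999 under the main prefix, windows that hold 1000 clusters each.

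Reads divided between near-identical contigs may raise the number of clusters found in pyometra alone, 437 against 84 found in normal alone. Of the 437, 60.0% had a count that was not whole, against 30.9% of the 7008 risen clusters also seen in normal. The 437 had a median effective length of 210.1 bases and the 7008 of 2273, so this contrast is not separated from length. Among clusters with whole counts, 175 were found in pyometra alone and 82 in normal alone. This does not exclude divided reads there, since all shared reads can be assigned to 1 contig. A processing step that kept contigs of one transcript separated by group would leave a normal-only counterpart for a pyometra-only cluster. The number of normal-only clusters per pyometra-only cluster was 0.192 (95% exact interval 0.150 to 0.243, counting clusters as independent). With 1 library left out, which relaxes the definition, it was 0.272 to 0.402 (0.373 without normal 2, 0.342 without pyometra 1 and 0.402 without pyometra 3). Most pyometra-only clusters thus had no such counterpart in any of these settings. This argues against the step for transcripts with enough reads in both groups. A counterpart of a risen transcript could have too few normal reads to be seen, so the step stays open for risen transcripts. The minimum of 10 counts behind this ratio, and the use of its interval, were chosen after the values were seen; with higher minimums the excess is larger, with 203 against 10 clusters at 30 counts and 93 against 0 at 100. RNA of another organism in the infected uterus stays open too, because the wide spread of ratios between libraries (SD 1.70) would also arise from a mixture of sources and the clusters carry no sequence; the disease itself, which the design names, was not tested apart from these.

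The higher FPKM sum in pyometra, 1.52 times that in normal, was weighed against 2 technical explanations. Loss of long transcripts by RNA degradation predicts a log2 fold change that falls with length. The Spearman correlation with effective length over the 31088 tested clusters was 0.052. The median log2 fold change was 0.07 for clusters under 500 bases, -0.18 between 500 and 1000 bases and 0.08 for those of 4000 bases or more. Over the 11662 clusters with a mean of at least 10 CPM the correlation was -0.014. These values argue against a general trend with the effective length of a cluster. That length need not be the length of a transcript, since what a cluster stands for was not settled. The effective length averaged over counts was lower in pyometra, 4115 against 4407 bases, the direction that such a loss would give. A loss of long transcripts therefore stays open. A few abundant clusters may carry part of the excess: without the 20 clusters of the highest mean FPKM the ratio of the group means was 1.29. Without the 100 highest it was 1.14. These clusters were not chosen by length. Without the 20 highest, clusters under 500 bases still summed to 121221 in normal and 301414 in pyometra. Those of 500 bases or more summed to 316846 and 264710, against 343715 and 356103 with all clusters. The 20 were thus not short clusters alone, and much of the excess in short clusters lay outside them. Without the 100 highest, clusters under 500 bases summed to 104484 in normal and 201825 in pyometra, and the longer ones to 274744 and 229124, and a change in the transcripts of the diseased tissue remains open.

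As a hypothesis, clusters with neighbouring numbers may hold related transcripts, so that the count of called clusters would exceed the number of separate transcripts. Over 16397 pairs of tested clusters with consecutive numbers under the main prefix, the Spearman correlation of the log2 fold changes was 0.199, against at most 0.018 in 100 shuffles of the partners. Of the 4168 pairs in which both were called, 61.9% went in the same direction, where 50.1% is given by the shares of rises and falls. The value lies between the levels of 0.3 and 0.1 set beforehand for and against the hypothesis, so it was not decided.

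Only 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, called as many as 14139 clusters, and the highest of the other splits called 0 (edgeR), with at most 541 clusters at an unadjusted p under 0.05 against 16517 in the real one. With 10 splits a share under 0.05 cannot be reached. Every other split also put normal and pyometra libraries together in both of its groups. The large difference between normal and pyometra then counted as spread within groups, so few calls could be made there. The low counts of the other splits therefore do not show how many clusters would be called without a difference.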
